A study of Mus musculus with 4 samples.

How the data were processed

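The series compares immune cells that had infiltrated MC38 tumours in WT mice and in knockout (KO) mice, with 2 libraries per genotype. Tumours had been digested with collagenases, dispase and DNase, and CD45-positive cells enriched on magnetic beads before droplet capture with a 10x Genomics 3' kit, per the labels' protocols. Enzymatic digestion can induce stress genes, and bead enrichment can leave cells without CD45 in a library. Each deposited matrix holds whole-number UMI counts per gene and barcode, not normalised, made with Cell Ranger (5.0.0 per the file headers, 5.0.1 per the submitters' processing notes) on mm10. Seurat 3.15 is also named in the submitters' processing notes, and its role is not given in the sources used here. The labels name the molecule as genomic DNA, although the protocol describes cDNA libraries and the values are UMI counts of genes. The gene tables hold 22620 genes, and how these were chosen is not given in the sources used here. Of their gene identifiers 22565 were found in the GENCODE annotation of mm10 that gave the coordinates. The lowest barcode had 500 UMIs, and the upstream rule for calling cells is not given in the sources used here. The labels carry replicate numbers 1 and 2 in both genotypes, with nothing to say that a number is shared.

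Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, which left out 32, 25, 19 and 25 barcodes by the first filter and 575, 553, 1117 and 846 by the other in WT 1, WT 2, KO 1 and KO 2. Scrublet, as implemented in scanpy 1.11.5, marked under 0.5% of each library and was taken not to have worked. In its place the barcodes with the highest scores were left out, 0.8% per 1000 barcodes, which removed 601, 622, 2369 and 722. This fallback rate scales with the loading and removed most from the largest library. Cells were scaled to 10000 counts, log transformed and clustered on 2000 variable genes, 30 principal components and 15 neighbours with Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15), with no integration of libraries. MHC, interferon, cell cycle, sex-linked, mitochondrial and ribosomal genes were kept out of the variable genes, so that clusters were not defined by genes on those compared lists.

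The 28 clusters were named from 17 sets of marker genes, and a class is called like its cell type because the names rest on markers alone. A name needed at least 3 of its markers in at least 10% of the cells, and a cluster with more markers of another class than its own among its top 10 genes stayed unnamed. The marker sets were fixed before the data were examined. Names went to the class with the highest mean standardised marker expression. A cluster with a median UMI count under 1/3 of its libraries' stayed unnamed where fewer than 3 of its own markers were among those top genes, and always where it scored for macrophages, monocytes or cDCs. The detection minimum, this low-UMI rule and a further split of clusters that scored almost alike for a pair of classes were set after the clusters had been seen. These rules left 21 clusters named and 7 unnamed. Their shares of immune-like cells in WT 1, WT 2, KO 1 and KO 2 were 20.6%, 21.5%, 0.95% and 2.02% for cluster 1, and 2.93%, 3.31%, 8.02% and 8.52% for cluster 3, a low-UMI cluster that scored for macrophages. They were 6.11%, 3.32%, 3.57% and 4.43% for cluster 12, also of low UMIs, and 0.281%, 1.07%, 7.52% and 6.53% for cluster 17, a low-UMI cluster that scored for CD8 T cells. Clusters 22 and 27 each held under 1% in every library, and cluster 15, with 818 cells and 8.92 CPM of Ptprc, the gene of CD45, was not counted as immune-like, nor was the fibroblast-like cluster 24 of 26 cells. Immune-like cells numbered 7817, 7859, 14743 and 8607. Free RNA was not removed.

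UMI counts were summed per class and library, because cells are not replicates, and the sums were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalisation and the robust quasi-likelihood test of KO against WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values are two-sided. Standard errors were computed from the log2 change and the F statistic. Classes with at least 20 cells in each library were tested, and B-like cells, plasmacytoid dendritic, gamma delta T and mast or basophil classes fell below that in some library. Shares were tested with the same model on numbers of cells over 12 classes, unnamed included, with all immune-like cells as the offset. Sums ranged from 75095 UMIs for NK-like cells of WT 1 to 73353000 for macrophage-like cells of KO 1, which sets how small a change could be called. Depth intervals cover counting error only.

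Gene lists, 28 in number, were fixed before the data were examined, and 27 were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Adjustment was over the lists measured in the class. With the preset correlation 19 lists passed in macrophage-like, 20 in monocyte-like, 15 in cDC-like, 18 in CD8 T-like, 15 in CD4 T-like and 18 in NK-like cells, all of 27, and 10 of 24 in neutrophil-like cells. With an estimated correlation none passed in any class, the lowest adjusted p being 0.0748, in monocyte-like cells, and fry passed 1 list in macrophage-like, 11 in monocyte-like and 7 in cDC-like cells and none in the others. The test with an estimated correlation rests on the 2 residual degrees of freedom of the 4 libraries, so few lists could pass it. Calls were lost with it even where the estimated correlation lay below the preset, as for the monocyte-like inflammatory (M1) list (-0.0140, adjusted p = 0.0748). Its failures alone therefore do not show that the preset is too low. In macrophage-like cells, however, the estimated correlation was 0.329 for the MHC class I list and 0.487 for the class II list. It was 0.740 for the interferon gamma response list and 0.871 for the cell cycle list. These estimates are imprecise but lie far above the preset of 0.01. The p-values at the preset correlation are therefore likely to be optimistic for such lists. The sex-linked list was not tested.

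Genes were named by a rule fixed before the data were examined: adjusted p under 0.05, a mean of at least 10 CPM and no overlap of the groups, taking the 10 largest rises and falls in macrophage-like cells and 5 of each in other classes. Added to these were members of the MHC lists in macrophage-like cells and up to 3 members per list with the smallest p. The targeted gene and 1 gene that the rule named in CD4 T-like cells are not reported here. Genes that complete a count of 5 or fewer, marker genes that passed, the dissociation stress, co-stimulation, inhibitory ligand and mitochondrial genome results, the hypoxia results in macrophage-like and CD8 T-like cells, and mt-Nd3 in CD4 T-like cells were chosen after their values were seen. Where a gene had 1 to 3 UMIs in a whole group, the ratio of summed CPM is given with an exact interval, and where it had none, a bound against 3 counts. Coordinates are those of mm10.

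The test was tried on simulated counts with 200 changed genes. Counts were drawn independently for each gene from a negative binomial at the trended dispersion of the fit, with no shift in cluster sizes. The rates below hold for that setting and need not hold for the libraries themselves. At the macrophage-like depth, over 12128 genes, 52.2% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, and 2.63% of the calls were false. At the CD8 T-like depth, over 7974 genes, the recovered shares were 6.06%, 36.9% and 95.5%, and 1.09% of the calls were false. A 1.5-fold change in CD8 T-like cells was therefore rarely detectable at this depth, and classes of lower depth were not simulated.

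Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, leaving out each library, thinning each cell to 1500 UMIs (which left out 106, 48, 204 and 87 shallower macrophage-like cells), keeping doublet calls, a mitochondrial limit of 10%, Leiden resolution 0.5, clusters from all variable genes, and macrophage-like and monocyte-like cells as 1 class. Total-count scaling, counting cluster 1 as macrophage-like, counting low-UMI clusters under their best class, shares of named cells alone, equal weights for the macrophage-like clusters, and share tests with the spread of each class alone were chosen after seeing the data. The grouping of clusters 5 and 7 against 6, 9 and 13 was also chosen then. The class of macrophage-like and monocyte-like cells together also took in the unnamed cluster 1.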

Results

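Single-cell RNA libraries were made from immune cells of MC38 tumours, grown from a mouse colon adenocarcinoma line, in wild-type (WT) mice and in knockout (KO) mice. CD45-positive cells had been enriched with magnetic beads, and the data comprised 2 WT and 2 KO libraries. WT libraries 1 and 2 held 9239 and 9369 barcodes with 94213071 and 112472244 UMIs. KO libraries 1 and 2 held 18324 and 10344 barcodes with 130466357 and 104900918 UMIs. After filtering, 8063, 8193, 14838 and 8776 cells remained, with median depths of 9824 and 11892 UMIs per cell in WT and 5462.5 and 7804 in KO. The number of animals behind each library is not given in the sources used here, so every p-value measures the spread between these libraries, which may be technical.

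The composition of the infiltrate was compared first. CD8 T-like cells made up 1.15 ± 0.591% of immune-like cells in WT and 6.54 ± 1.34% in KO (SD, n = 2 libraries each), and NK-like cells 0.459 ± 0.251% and 2.36 ± 0.193%. Monocyte-like cells made up 4.12 ± 0.548% in WT and 12.2 ± 0.377% in KO, and macrophage-like cells 53.8 ± 1.52% and 48.7 ± 1.10%. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes were 2.51 for CD8 T-like cells (adjusted p = 6.9e-06), 2.36 for NK-like cells (0.00933), 1.57 for monocyte-like cells (1.1e-06) and -0.14 for macrophage-like cells (0.00562). CD4 T-like cells (2.33 ± 0.578% and 3.10 ± 0.564%), conventional dendritic cell-like (cDC-like) cells (5.14 ± 0.245% and 3.30 ± 0.232%), neutrophil-like cells (1.42 ± 0.646% and 1.65 ± 1.08%) and B-like cells (0.550 ± 0.507% and 0.226 ± 0.00698%) did not pass, with adjusted p of 0.479, 0.165, 0.818 and 0.386.

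These share tests pool the spread of all 12 classes, which makes their p-values optimistic: an exact permutation test of 2 against 2 libraries cannot go below p = 0.333. With the spread of each class alone no share passed, the adjusted p being 0.121 for CD8 T-like, NK-like and macrophage-like cells and 0.0583 for monocyte-like cells. The NK-like call ended without WT 1, KO 1 or KO 2 (log2 change 1.89, 2.44 and 2.27), and the macrophage-like call without WT 2 or KO 1 (-0.11 and -0.12). The macrophage-like change also became 0.04 with TMM scaling over the classes. With doublet calls kept the monocyte-like change became -0.61 and passed in the opposite direction (adjusted p = 0.000424). A cluster like the unnamed cluster 1 took the monocyte name in that setting. The B-like change was 0.24 without WT 1 and -2.0 without WT 2, where it passed, and the neutrophil-like change was -0.18 without WT 2 and -0.69 without KO 1. Unnamed clusters held 30.3 ± 0.566% of immune-like cells in WT and 20.9 ± 1.02% in KO. Of these, cluster 1, led by Chil3, Ear2, Fn1 and Ccr2, held 20.6% and 21.5% in WT against 0.95% and 2.02% in KO. Counted as macrophage-like, it brought that class to 73.4% and 76.3% in WT and 48.9% and 51.5% in KO. Cluster 1 scored 0.455 for macrophages and 0.360 for monocytes, and counting it as monocyte-like was not tried. The monocyte-like rise therefore depends on leaving it unnamed. KO libraries were also shallower per cell, a gap that can set which barcodes reach a named cluster.

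**Figure D1:**
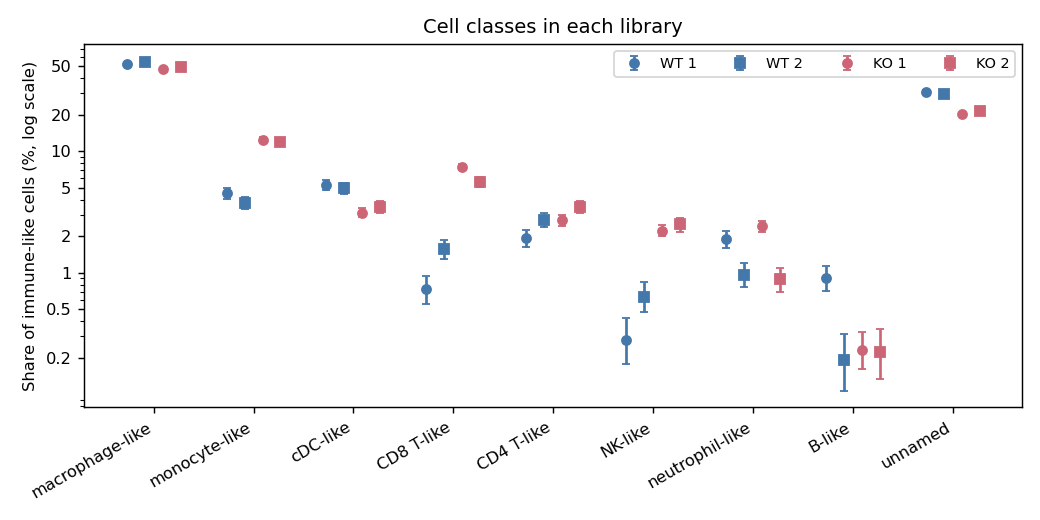
Share of immune-like cells (percent, log scale) held by each class in each of the 4 libraries. Points are libraries and bars are exact 95% binomial intervals for counting error. CD8 T-like, NK-like and monocyte-like cells lie higher in both KO libraries than in both WT libraries, and unnamed clusters lie lower.

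The series title is about macrophages, and macrophage-like cells gave the main comparison. Cnn3, an actin-binding calponin, rose by 3.0 ± 0.15 log2 units (SE), from 3.02 ± 0.495 to 24.3 ± 2.30 CPM (counts per 1e6 UMIs; SD, n = 2 libraries each). Ly6a rose by 2.66 ± 0.16, from 147 ± 18.5 to 932 ± 156 CPM, and the interferon-inducible GTPases Iigp1 and Gbp4 rose by 2.45 ± 0.15 and 2.43 ± 0.13. The other large rises were those of Il18bp, which encodes a soluble inhibitor of interleukin-18 (2.73), the interferon-induced Ifitm1 (2.69), Calhm6 (2.46), the uridine phosphorylase Upp1 (2.25), the IgG receptor Fcgr4 (2.10) and H2-T10 (2.79). H2-T10 is annotated as a polymorphic pseudogene within a multigene family, so its count is uncertain. Fcrls fell by 2.60 ± 0.15, from 250 ± 51.0 to 41.3 ± 2.18 CPM, and the fractalkine receptor Cx3cr1 fell by 2.08 ± 0.09, from 202 ± 1.55 to 47.9 ± 2.20 CPM. Ltc4s, the leukotriene C4 synthase (-2.04), Htra3 (-1.94), Col14a1 (-1.69), the linker histones H1f1 (-1.48) and H1f5 (-1.29), the receptor-modifying protein gene Ramp1 (-1.31), Pxdc1 (-1.27) and Gpr34 (-1.25) also fell.

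Across 12223 genes tested in macrophage-like cells, 1057 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 538 higher and 519 lower in KO. With total counts in place of TMM scaling, which moved the median log2 change of all genes to -0.15, 1448 passed, 377 higher and 1071 lower. The count was 1775 without WT 2 and 655 without KO 1. Leaving out 1 library ended the call of 7 of the 20 genes above: H2-T10, Il18bp, Calhm6 and H1f5 without either WT library, Upp1 without either KO library, Ifitm1 without WT 1 or KO 1 and Ltc4s without WT 1, KO 1 or KO 2, with adjusted p up to 0.413. Different clusters held most of this class in the 2 groups. Clusters 5 and 7 held 56.3% and 50.3% of macrophage-like cells in WT and 4.97% and 10.3% in KO, whereas clusters 6, 9 and 13 held 9.95% and 17.7% in WT and 74.6% and 65.9% in KO. Fcrls and Cx3cr1 are among the leading genes of cluster 7, Il18bp, Calhm6 and Fabp5 of cluster 6, H1f5 and Mki67 of cluster 8, Ctsc of cluster 9 and Htra3 of the unnamed cluster 1. Cluster 8, a cycling cluster, held 11.4% and 13.1% in WT and 4.50% and 6.90% in KO. With the clusters weighted equally in every library, 265 genes passed. Here CPM were averaged over the 8 clusters, increased by 1, log2 transformed and tested with limma's moderated t test. Clusters with high CPM weigh more in such an average, and the test is not that of edgeR. Cluster sizes are therefore not all that differs between these values and the main ones. Of the 20 genes above, 15 had changes smaller by more than 1.5 times with these weights. Cnn3 was then at 1.41, Ly6a at 1.14, Iigp1 at 1.04, Gbp4 at 1.13, Calhm6 at 0.99, Cx3cr1 at -1.11 and H1f5 at -0.59, and all 7 still passed. Fcrls and Gpr34 lost their calls (-1.16 and -0.45, adjusted p = 0.0737 and 0.101). So did 17 of the 32 other passing macrophage-like genes whose values are given below: Nlrc5, H2-DMa, Ifi30, Ifi44, Oas1a, Tnf, Pdcd1lg2, Cd86, Cd80, Cd40, Icosl, Hmgb2, Mki67, Kif11, Ctsc, Ctsd and Hexa. Oasl2 changed direction.

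Antigen presentation genes are named in the series title. Of 17 measured members of the MHC class I presentation list, 15 rose in KO macrophage-like cells and none fell (16 adjusted over the list alone), with a median log2 change of 1.01. The class I heavy chains H2-K1 (chromosome 17, 33996017 to 34000347) and H2-D1 (chromosome 17, 35262730 to 35267499) rose by 1.31 ± 0.15 and 1.32 ± 0.17 log2 units, from 888 ± 129 to 2206 ± 274 CPM and from 1333 ± 281 to 3334 ± 340 CPM. B2m, the light chain they share (chromosome 2, 122147686 to 122153083), rose by 0.93 ± 0.13, from 2337 ± 239 to 4460 ± 422 CPM. The peptide transporter subunit Tap1 rose by 1.23 ± 0.13 and Nlrc5, the transactivator of class I genes, by 1.17 ± 0.11, whereas the chaperone calnexin, Canx, differed by -0.14 (adjusted p = 0.441). The classical class I genes are similar paralogs, so their counts are uncertain where a read matches several of them. The list passed limma's camera test with its preset correlation (adjusted p = 1.3e-30). The adjusted p was 0.234 with an estimated correlation and 0.0573 in fry, so the call was lost in both. With equal cluster weights the list passed (2.2e-21) with a median of 0.53, H2-K1, H2-D1, B2m and Tap1 were at 0.80, 0.85, 0.53 and 0.67, and Nlrc5, at 0.50, lost its call (0.0957).

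Of 14 measured members of the MHC class II presentation list, 3 rose and none fell in macrophage-like cells (6 adjusted over the list alone), with a median log2 change of 0.70. The members that rose were the lysosomal protease Ctss (1.02 ± 0.13), H2-DMa, a subunit of the class II peptide exchange factor H2-DM (0.73 ± 0.16), and the lysosomal thiol reductase Ifi30 (0.52 ± 0.11). The invariant chain Cd74 (chromosome 18, 60803848 to 60812652) went from 3878 ± 1547 to 8166 ± 843 CPM, a log2 difference of 1.07 ± 0.29 that did not pass (adjusted p = 0.0950). The class II chains H2-Ab1, H2-Aa and H2-Eb1 differed by 1.09, 1.05 and 1.02 with adjusted p of 0.112, 0.129 and 0.159. Without WT 1 the differences of these 4 genes were smaller (0.71, 0.71, 0.67 and 0.62), in the order Cd74, H2-Ab1, H2-Aa and H2-Eb1. Without WT 2 they were larger (1.56, 1.61, 1.59 and 1.58, in the same order). Their size thus depended on which WT library was kept. The call of Ifi30 ended without WT 1, KO 1 or KO 2 and that of H2-DMa without KO 1 (adjusted p up to 0.0864). The list passed camera with the preset correlation (adjusted p = 1.9e-05), with an adjusted p of 0.331 with an estimated correlation and 0.145 in fry. With equal cluster weights the list passed (0.00771) with a median of 0.20, Ctss was at 0.56, and H2-DMa (0.27, adjusted p = 0.221) and Ifi30 (0.14, 0.447) lost their calls.

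**Figure D2:**
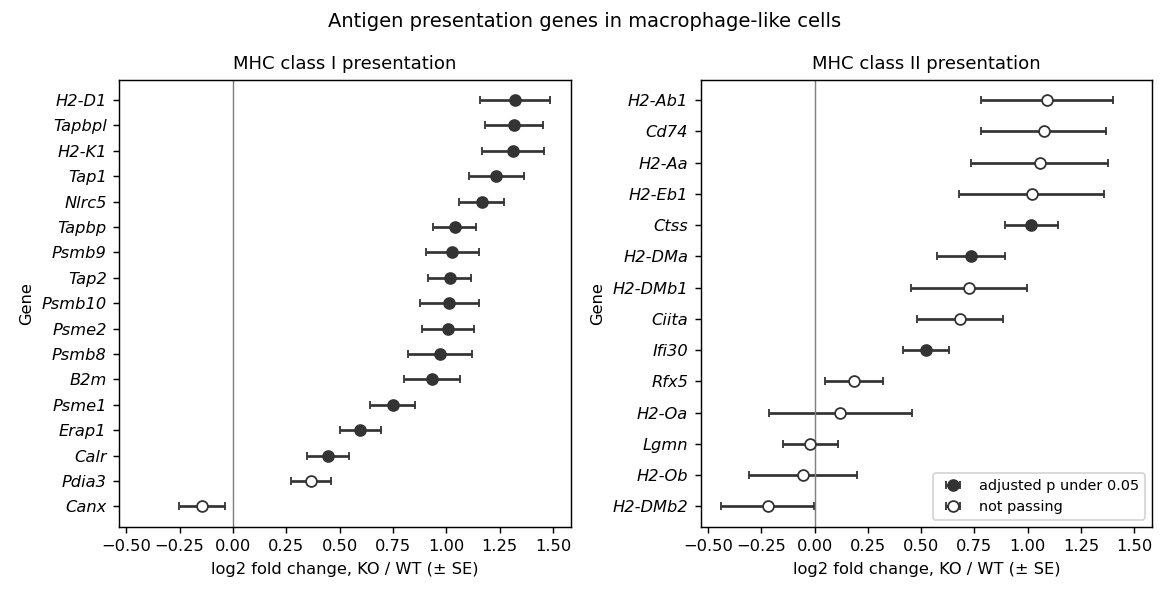
Log2 fold change (KO over WT) of each measured member of the MHC class I and class II presentation lists in macrophage-like cells, from 2 libraries per group. Points are edgeR estimates, bars are standard errors, and filled points passed an adjusted p of 0.05. On the class I list 15 of 17 genes passed, and on the class II list 3 of 14.

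Interferon gamma response genes rose together in macrophage-like cells: 15 of 19 measured members rose and none fell (19 adjusted over the list alone), with a median log2 change of 1.66. Gbp4, Iigp1 and the cytokine signalling inhibitor Socs1 changed by 2.43, 2.45 and 1.75. The list passed camera (adjusted p = 3.0e-57), with an adjusted p of 0.234 with an estimated correlation. With equal cluster weights the median was 0.70, which is 42.2% of its value, and the list passed (1.5e-19). On the type I interferon list 3 of 21 members rose, Ifi44 (1.53), Oas1a (0.46) and Oasl2 (0.55), and 2 fell, Mx1 and Isg20, with a median of -0.13; adjusted over the list alone, 3 rose and 3 fell. Camera placed this list higher in KO, against the sign of its median, and it did not pass (adjusted p = 0.703). The list passed lower without WT 1 (adjusted p = 0.00835) and with equal cluster weights (6.5e-05). It passed higher without WT 2 (0.0145), with doublet calls kept (0.0434), at Leiden resolution 0.5 (0.00356), with clusters from all variable genes (1.0e-05) and with cluster 1 counted (0.0111). It also passed higher with macrophage-like and monocyte-like cells as 1 class, which took in cluster 1 (1.3e-09, and 0.241 with an estimated correlation). There 10 of 21 members rose and none fell (12 adjusted over the list alone, with a median of 0.54). The direction of this list is therefore left open. Oasl2 lost its call without WT 1 or KO 1 and Oas1a without WT 1 or KO 2 (adjusted p up to 0.110), and with equal cluster weights Oasl2 was at -0.15. On the inflammatory (M1) list 5 of 16 rose and none fell (13 adjusted over the list alone; median 0.58, adjusted p = 5.9e-13, and 0.267 with an estimated correlation), among them the nitric oxide synthase Nos2 (1.20 ± 0.11), the chemokine Ccl4 (1.51 ± 0.15) and Tnf (0.77 ± 0.09); the others were the chemokines Cxcl1 and Cxcl2. None of 14 members of the alternative activation (M2) list passed in edgeR (none adjusted over the list alone), although 2 were higher and 1 lower both at an unadjusted p under 0.05 and in DESeq2. Its median was -0.36 (adjusted p = 0.590), and the adjusted p of this list was 5.2e-05 without WT 2. The genes of PD-L1, Cd274, and PD-L2, Pdcd1lg2, rose by 1.09 ± 0.10 and 1.98 ± 0.27, and they were the 2 of 8 members of the inhibitory ligand list to rise, with none falling (2 higher and 1 lower adjusted over the list alone; median 0.07, adjusted p = 0.0159, and 0.267 with an estimated correlation). The call of Pdcd1lg2 ended without either WT library (adjusted p up to 0.238), and that of the list without WT 2 (0.211) or with equal cluster weights (0.349). On the co-stimulation list 3 of 8 rose, the co-stimulatory ligand genes Cd86 (0.75 ± 0.13) and Cd80 (0.39 ± 0.09) and the receptor gene Cd40 (0.67 ± 0.12), and 1 fell, the ligand gene Icosl (-0.55 ± 0.13). Adjusted over the list alone 4 rose and 1 fell, and the median was 0.35 (adjusted p = 0.00501, 0.331 with an estimated correlation and 0.238 with equal cluster weights). Cd80 lost its call without WT 1, KO 1 or KO 2 and Icosl without WT 1 or KO 2 (adjusted p up to 0.193).

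**Figure D3:**
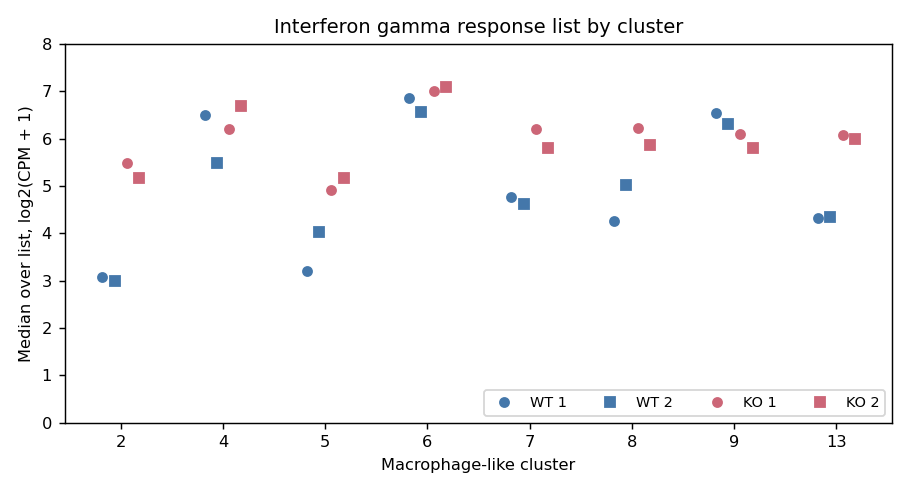
Median over the interferon gamma response list of log2(CPM + 1) in each of the 8 macrophage-like clusters, by library. Each point is 1 library. Both KO libraries lie above both WT libraries in 6 of the 8 clusters, clusters 4 and 9 being the exceptions.

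Cholesterol synthesis genes fell in KO macrophage-like cells, 11 of 15 measured members passing lower and none higher (15 adjusted over the list alone; median -0.82, adjusted p = 1.5e-15, and 0.267 with an estimated correlation). Sc5d, a sterol desaturase, changed by -0.99 ± 0.12, the squalene synthase gene Fdft1 by -0.90 ± 0.14 and the sterol sensor Insig1 by -0.73 ± 0.11. Cell cycle genes also fell, 23 of 44 passing lower and none higher (40 adjusted over the list alone; median -0.68, adjusted p = 1.4e-22, and 0.331 with an estimated correlation), with Hmgb2, Mki67 and Kif11 at -0.83, -0.92 and -1.12; the call of Kif11 ended without WT 1 (adjusted p = 0.0630). With equal cluster weights the list lost its call (median -0.05, adjusted p = 0.779), as did these 3 genes. The cycling cluster 8 held a smaller share in KO, but these values do not divide the fall between cluster sizes and changes within clusters. Changes in clusters with low levels of these genes carry little weight in that average and are not separated. On the lysosome list 6 of 28 rose and none fell (17 adjusted over the list alone; median 0.33, adjusted p = 3.2e-07, and 0.267 with an estimated correlation), including the cathepsins Ctsc (0.73) and Ctsd (0.64) and the hexosaminidase Hexa (0.62). Ctsd and Hexa lost their calls without KO 1 (adjusted p = 0.101 and 0.0501). With equal cluster weights the medians of these lists were -0.82 for cholesterol synthesis, -0.05 for cell cycle and 0.11 for lysosome. On the hypoxia list 2 of 13 fell, Ankrd37 and Slc2a1, and none rose (4 lower and 1 higher adjusted over the list alone; median -0.32, adjusted p = 0.0303, and 0.603 with an estimated correlation). It lost its call in 10 other alternatives, among them leaving out WT 1 (0.198), KO 1 (0.0578) or KO 2 (0.0768) and equal cluster weights (0.166). The fatty acid binding protein gene Fabp5 rose by 0.89 ± 0.11. Of 27 mitophagy genes none passed in edgeR (none adjusted over the list alone; median 0.03, adjusted p = 0.508), with 4 higher and 1 lower at an unadjusted p under 0.05 and 2 higher in DESeq2.

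T cell transcripts were higher in the same macrophage-like sums. Of 9 measured CD8 T cell markers 7 rose, with a median log2 change of 2.75, and on the cytotoxic effector list 5 of 19 rose and none fell (16 adjusted over the list alone; median 2.66, adjusted p = 2.6e-17, and 0.267 with an estimated correlation), namely Ccl4, Cst7, Gzmb, Ifng and Tnf. Ifng, which lymphocytes secrete, went from 0.103 ± 0.0917 to 2.56 ± 0.464 CPM. From the T cell receptor genes, the share of T cell RNA in these sums was 0.0428% and 0.101% in WT and 0.372% and 0.246% in KO.

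In monocyte-like cells inflammatory genes were higher in KO. The neutrophil-attracting chemokines Cxcl1 and Cxcl3 rose by 3.57 ± 0.20 and 2.64 ± 0.15 log2 units, from 11.3 ± 1.52 to 135 ± 27.1 CPM and from 45.3 ± 1.95 to 281 ± 52.9 CPM. Inhba, the activin A subunit, rose by 3.12 ± 0.13, from 130 ± 19.9 to 1139 ± 5.19 CPM, the protein C receptor gene Procr by 3.39 ± 0.27 and Slc4a11 by 2.64 ± 0.49. The largest falls were those of Igfbp6 (-1.95 ± 0.30), Cx3cr1 (-1.82 ± 0.13), the integrin Itga6 (-1.69 ± 0.28), Tmem273 (-1.67 ± 0.31) and Stxbp6 (-1.67 ± 0.35). Of 9578 genes tested 647 passed in edgeR, 435 higher and 212 lower, and 310 passed in DESeq2. With total counts, which moved the median of all genes to -0.09, 684 passed, 338 higher and 346 lower. The count was 228 without WT 1 and 431 without KO 1. Inhba and Cxcl1 are among the leading genes of the macrophage-like cluster 2. Slc4a11 and Stxbp6 lost their calls without either WT library and Igfbp6 and Tmem273 without WT 1, with adjusted p up to 0.230.

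On the inflammatory (M1) list 13 of 16 measured members rose in monocyte-like cells and none fell (14 adjusted over the list alone; median 1.60, adjusted p = 1.8e-67, and 0.0748 with an estimated correlation), with Nos2 at 2.37 ± 0.13. Hypoxia genes rose, 7 of 12 passing higher (8 adjusted over the list alone; median 0.56, adjusted p = 1.6e-11, and 0.0997 with an estimated correlation), among them the lipid droplet gene Hilpda (2.02 ± 0.18), Ndrg1 (1.19 ± 0.12) and the angiogenic factor Vegfa (0.89 ± 0.14). With clusters made from all variable genes, the hypoxia list was lower (adjusted p = 0.00726) and Ndrg1 was at -0.26, and with doublet calls kept the list lost its call (0.205). On the oxidative stress list 8 of 14 rose (8 adjusted over the list alone; median 0.58, adjusted p = 2.7e-08, and 0.141 with an estimated correlation), including the cystine transporter Slc7a11 (1.41 ± 0.14) and the ferritin heavy chain Fth1 (1.19 ± 0.14). MHC class I genes rose, 10 of 17 passing higher (13 adjusted over the list alone; median 0.45, adjusted p = 9.8e-09, and 0.237 with an estimated correlation), with H2-K1 at 0.81, H2-D1 at 0.65 and B2m at 0.60; B2m lost its call without WT 1 or KO 1 (adjusted p up to 0.105). Of 19 interferon gamma response genes 7 rose and 1, Ciita, fell (13 and 1 adjusted over the list alone; median 0.80, adjusted p = 7.7e-13, and 0.214 with an estimated correlation), with Gbp4 at 1.24 and Igtp at 0.96, and Cd274 rose by 1.25 ± 0.11. In the same sums 3 of 16 macrophage markers rose, Pf4, C1qb and Spp1, and 1 fell, Mrc1 (median 0.09, 11 positive), and 3 of 6 CD8 T cell markers rose, Trac, Cd3d and Cd8a (median 2.42), and 10 of 17 cytotoxic effector genes (14 adjusted over the list alone; median 1.97, also with 1 gene without UMIs in WT set to its bound; adjusted p = 7.6e-23, and 0.0997 with an estimated correlation), with 6 of the 17 passing in DESeq2. DESeq2 also called 8 interferon gamma response genes higher and none lower, so the fall of Ciita was not called there.

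cDC-like cells also carried interferon gamma response genes at higher levels in KO, 16 of 19 passing higher and none lower (18 adjusted over the list alone; median 1.32, adjusted p = 2.5e-67, and 0.168 with an estimated correlation). Iigp1 rose by 2.47 ± 0.14 log2 units, the chemokine Cxcl10 by 2.14 ± 0.10, from 78.3 ± 1.82 to 344 ± 0.0202 CPM, and Igtp by 2.04 ± 0.13. The largest rises were those of Inhba (3.19 ± 0.33), Cxcl1 (2.56 ± 0.32), Ly6i (2.55 ± 0.18), Iigp1 and Gm4951 (2.45 ± 0.28). Trp53i11 (-2.33 ± 0.22), Gfra2 (-2.26 ± 0.48), Ppp1r1a (-2.13 ± 0.26), Asgr2 (-2.13 ± 0.31) and Cgnl1 (-1.88 ± 0.34) fell the most; Asgr2 and H2-DMb2 are leading genes of the larger cDC-like cluster, Ly6i leads the monocyte-like cluster, and Inhba and Cxcl1 are leading genes of the macrophage-like cluster 2. MHC class I genes rose, 13 of 17 passing higher (15 adjusted over the list alone; median 0.59, adjusted p = 1.0e-21, and 0.284 with an estimated correlation), with Tap1, Psme2 and Psmb10 at 0.88, 0.82 and 0.80. Of 14 class II genes only H2-DMb2 passed, with a change of -0.53 ± 0.12 (1 adjusted over the list alone; median -0.003, adjusted p = 0.692). Cell cycle genes fell, 18 of 44 passing lower (26 adjusted over the list alone; median -0.76, adjusted p = 2.0e-24, and 0.284 with an estimated correlation), with Ube2c at -1.73, Cenpf at -1.60 and Top2a at -0.86, although Top2a was at 0.07 with clusters made from all variable genes. In DESeq2 12 of the cell cycle genes passed lower.

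Of 9780 genes tested in cDC-like cells 535 passed in edgeR, 324 higher and 211 lower, and 275 passed in DESeq2. The count was 208 without WT 1, 356 without WT 2 and 863 without KO 2. Gfra2, Cgnl1 and H2-DMb2 lost their calls without WT 1 and Asgr2 without either WT library, with adjusted p up to 0.192. Lymphocyte and macrophage transcripts moved in these sums as well. Of 15 macrophage markers 12 had positive log2 changes (median 0.29), and 7 of 15 cytotoxic effector genes rose (11 higher and 1 lower adjusted over the list alone; median 1.34, adjusted p = 8.7e-13, and 0.227 with an estimated correlation), with Nkg7 at 2.74 ± 0.38 and Gzmb at 3.33 ± 0.51.

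CD8 T-like cells had higher transcripts of effector molecules in KO. The chemokine Ccl3 rose by 3.60 ± 0.26 log2 units, from 70.8 ± 44.6 to 991 ± 6.46 CPM, and perforin, Prf1, by 2.37 ± 0.25, from 112 ± 34.0 to 620 ± 161 CPM. On the cytotoxic effector list 7 of 20 rose and none fell (14 adjusted over the list alone; median 1.19, adjusted p = 1.9e-41, and 0.118 with an estimated correlation), including Nkg7 (1.08 ± 0.14), a leading gene of the cluster. On the T cell exhaustion list 4 of 16 rose and none fell (11 adjusted over the list alone; median 1.09, adjusted p = 2.5e-19, and 0.170 with an estimated correlation), with the inhibitory receptors Havcr2 and Ctla4 at 2.27 ± 0.32 and 1.29 ± 0.19, Rgs16 at 1.71 ± 0.21 and Nr4a2 as the remaining member. On the hypoxia list 1 of 11 rose, Hilpda, and none fell (5 adjusted over the list alone; median 0.70, adjusted p = 2.7e-06, and 0.253 with an estimated correlation), and with doublet calls kept the list did not pass and changed direction (0.907). Slamf6, carried by less differentiated T cells, fell by 1.65 ± 0.31. H2-T10 (2.48), Inhba and Slc17a6 also rose. Inhba and Slc17a6 had only 2 and 3 UMIs in WT, with CPM ratios of KO to WT of 11.4 (exact 95% counting interval 3.10 to 94.6) and 11.5 (3.90 to 56.2). Krt83 (-2.51), Tmem176a (-2.17), Tnfsf8, the CD30 ligand (-2.08), Tmem176b (-2.08) and Ramp1 (-1.91) fell.

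Of 8190 genes tested in CD8 T-like cells 57 passed in edgeR, 45 higher and 12 lower, from 57 and 123 cells in WT and 1103 and 481 in KO. The count was 123 without WT 1, 96 without WT 2 and 110 without KO 2. Tmem176b and H2-T10 lost their calls without either WT library, and Ramp1, Slc17a6 and Inhba without WT 2, with adjusted p up to 0.501. No MHC class I gene passed among 17 in edgeR, at an unadjusted p under 0.05 or in DESeq2 (none adjusted over the list alone; median 0.09, adjusted p = 0.218), although the list passed higher with doublet calls kept (1.1e-05) and with no filter on low counts (0.0485). No interferon gamma response gene passed among 17 in edgeR or DESeq2, with 4 higher at an unadjusted p under 0.05 (2 adjusted over the list alone; median 0.17, adjusted p = 0.0531). That list passed higher without KO 2 (0.000664), with doublet calls kept (1.8e-11), at a mitochondrial limit of 10% (1.8e-06), with low-UMI clusters counted (8.8e-05) and with clusters from all variable genes (0.0370). Macrophage markers moved with the genotype in these sums, 14 of 15 having positive log2 changes with a median of 0.57, and 3 passing, Arg1, Spp1 and Pf4. Arg1 and Spp1, expressed by macrophages, were higher by 1.20 ± 0.21 and 1.14 ± 0.18. Inhba, which also rose, is a leading gene of the macrophage-like cluster 2. Arg1 lost its call without WT 2 or KO 1 and Spp1 without KO 1 (adjusted p up to 0.175), and with doublet calls kept they were at -0.05 and -0.51.

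In CD4 T-like cells, whose cluster was led by Tnfrsf4, Ctla4 and Foxp3, Ramp1 fell by 2.59 ± 0.22 log2 units, from 181 ± 11.9 to 29.7 ± 5.05 CPM (adjusted p = 5.6e-09). Clec12a (2.87 ± 0.66), complement C3 (2.62 ± 0.60) and the prostaglandin synthase Ptgs2 (2.57 ± 0.42) rose, as did Cdk5rap1 and the granzyme Gzmd, with only 2 and 3 UMIs in WT and CPM ratios of KO to WT of 13.6 (exact 95% counting interval 3.53 to 116) and 9.75 (3.12 to 49.1). Flywch2, with 23 UMIs in WT and 2 in KO (ratio of WT to KO 16.9, 4.18 to 148), Jcad (-1.78 ± 0.37) and Ptpn5 (-1.40 ± 0.35) fell. The co-stimulatory receptor Icos rose by 0.61 ± 0.13 and was the 1 gene of 14 on the regulatory T cell list to pass (1 adjusted over the list alone; median 0.05, adjusted p = 0.287). Of 7493 genes tested 64 passed in edgeR, 51 higher and 13 lower, 148 without WT 2, and 19 passed in DESeq2. Leaving out 1 library ended the call of 8 of the 9 genes named for the size of their change, Ramp1 being the exception, and that of Icos, with adjusted p up to 0.911. Each of the 2 WT and 2 KO libraries ended at least 1 of these calls. Macrophage markers were again higher, 14 of 14 with positive log2 changes and a median of 1.0, Arg1 and Spp1 passing, and 4 of 13 genes of the lipid-associated macrophage list rose (4 adjusted over the list alone; median 0.51, adjusted p = 1.2e-11, and 0.426 with an estimated correlation), namely Cd63, Ctsl, Lgals3 and Spp1. Arg1 rose by 1.34 ± 0.18 in the same sums. C3 is also a leading gene of the macrophage-like cluster 6, and carried-in RNA is not separated from a change in CD4 T-like cells.

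NK-like cells numbered 22 and 50 in WT and 328 and 215 in KO. Chemokine genes were higher, 9 of 16 passing (14 adjusted over the list alone; median 1.77, adjusted p = 7.5e-30, and 0.286 with an estimated correlation), with Ccl4 at 3.11 ± 0.39. Cxcl10, Cxcl1 and Tmsb15a also rose but had only 2, 1 and 1 UMIs in WT, with CPM ratios of KO to WT of 11.9 (exact 95% counting interval 3.22 to 99.2), 15.9 (2.77 to 636) and 17.3 (3.02 to 690). Cd300c2 and Camk2b had 0 UMIs in both WT libraries and 72 and 69 in KO, at least 4.71-fold and 4.51-fold higher against a floor of 3 counts over the WT group. Tmsb15a was lower in KO with doublet calls kept (-1.19). Klk8 (-2.13 ± 0.48), Tmem254a (-1.84 ± 0.28), the mitochondrially encoded mt-Nd3 (-1.70 ± 0.24), the T cell receptor component Cd3g (-1.66 ± 0.38) and Cxcr6 (-1.62 ± 0.38) fell. Of 18 cytotoxic effector genes 2 rose (2 adjusted over the list alone; median 0.49, adjusted p = 3.3e-05, and 0.286 with an estimated correlation), the chemokines Ccl3 and Ccl4, and this list lost its call with doublet calls kept (0.214). Dissociation stress genes were higher too, 4 of 18 passing (10 adjusted over the list alone; median 0.82, adjusted p = 4.7e-12, and 0.286 with an estimated correlation), namely Dusp1, Ier2, Jun and Zfp36. In DESeq2 only 2 of the chemokine genes, 1 of the cytotoxic effector genes and none of the dissociation stress genes passed. All 13 measured macrophage markers had positive log2 changes in these sums (median 1.61), of which Pf4, C1qc (1.66 ± 0.35) and Arg1 (1.7 ± 0.31) passed. Cxcl10 is also a leading gene of the monocyte-like cluster 10 and Cxcl1 of the macrophage-like cluster 2. RNA carried in from such cells is not separated from a change in NK-like cells. Of 6613 genes tested 40 passed in edgeR, 33 higher and 7 lower, and 4 passed in DESeq2. The count was 272 without WT 1 and 10 without KO 1, and leaving out WT 2, KO 1 or KO 2 ended the call of each of the 10 genes with the largest changes in at least 1 case (adjusted p up to 1.0). C1qc and Arg1 lost theirs without WT 2 or KO 1.

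In neutrophil-like cells the interferon-induced chemokine Cxcl9 rose by 3.61 ± 0.45 log2 units, from 17.3 ± 5.49 to 224 ± 10.3 CPM, and Ccl5 by 3.87 ± 0.47. Interferon gamma response genes were higher, 4 of 13 passing (10 adjusted over the list alone; median 1.96, adjusted p = 2.5e-26, and 0.344 with an estimated correlation), among them the transcription factor Irf1 at 2.21 ± 0.38 and Irgm1 at 1.96 ± 0.37, beside Cxcl9 and Socs1. Of 16 MHC class I genes 3 rose (13 adjusted over the list alone; median 1.14, adjusted p = 1.1e-15, and 0.344 with an estimated correlation), with Tap1 at 1.93 ± 0.40 beside the proteasome genes Psmb8 and Psme2; in DESeq2 1 of these 16 genes passed, and 3 of the 13 interferon gamma response genes. Tagap1 (chromosome 17, 6955011 to 6961156) rose from 2 UMIs in WT to 58 in KO (CPM ratio 18.4, exact 95% counting interval 4.86 to 155), Ms4a7 by 2.68 ± 0.54 and Il18bp by 2.47 ± 0.47. Rhov (-2.25 ± 0.50), Retnlg (-1.92 ± 0.34), Lcn2 (-1.66 ± 0.37), Fn1 (-1.63 ± 0.33) and Adssl1 (-1.56 ± 0.38) fell; Retnlg leads a neutrophil-like cluster, and Rhov and Lcn2 lead the unnamed cluster 27. Of 14 macrophage markers 2 passed higher, Ms4a7 and Apoe (median 0.13). Cxcl9 is also a leading gene of the macrophage-like cluster 9 and the monocyte-like cluster 10, and Il18bp and Ms4a7 of the macrophage-like cluster 6. Free RNA was not removed, so RNA carried in from such cells is not separated from a change in neutrophil-like cells. Of 2602 genes tested 30 passed in edgeR, 23 higher and 7 lower, and 11 in DESeq2. The count was 136 without WT 1 and 50 without WT 2, and leaving out 1 library ended the call of 7 of the 10 genes with the largest changes, KO 1 in 6 cases and WT 1, WT 2 or KO 2 in others, with adjusted p up to 0.958. Fn1 was at 0.02 with doublet calls kept.

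Dissociation stress genes, which the digestion of the tumours can induce, were also examined in the other 6 classes. In CD8 T-like cells 2 of 18 rose, Btg2 and Ier3, and none fell (8 adjusted over the list alone; median 0.61, adjusted p = 7.4e-11, and 0.318 with an estimated correlation). In macrophage-like cells 3 of 19 rose, Dusp1, Fosb and Socs3 (4 higher and 1 lower adjusted over the list alone; median 0.17, adjusted p = 0.00773, and 0.331 with an estimated correlation). In monocyte-like cells 4 of 18 rose, Egr1, Fosb, Ier3 and Socs3 (6 higher and 1 lower adjusted over the list alone; median 0.24, adjusted p = 0.00796, and 0.237 with an estimated correlation). The macrophage-like list lost its call without WT 2 (0.0863) or KO 1 (0.106), and the monocyte-like list without WT 1 (0.0850) or at Leiden resolution 0.5 (0.0624). In CD4 T-like cells none of 18 passed in edgeR or DESeq2, with 8 higher at an unadjusted p under 0.05 (6 adjusted over the list alone; median 0.42, adjusted p = 6.9e-05, 0.356 with an estimated correlation and 0.470 after thinning). In neutrophil-like cells none of 18 passed in either, with 5 lower at an unadjusted p under 0.05 (2 lower adjusted over the list alone; median -0.29, adjusted p = 0.00399, and 0.361 with an estimated correlation). In cDC-like cells Egr1 fell alone among 18 (1 higher and 1 lower adjusted over the list alone; median 0.06, adjusted p = 0.981). Handling and genotype are not separated by these values.

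**Figure D4:**
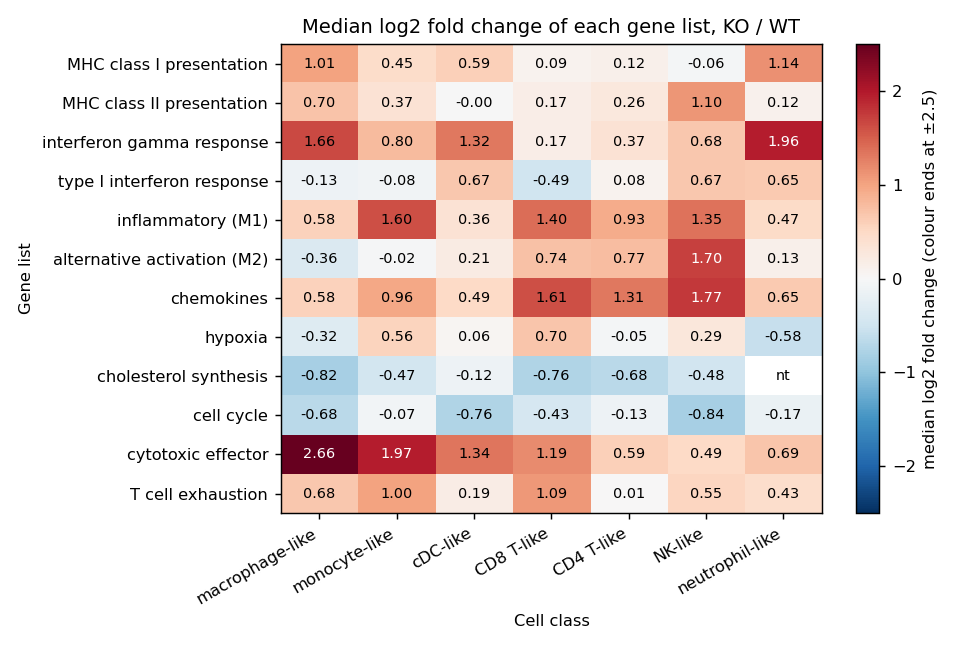
Median log2 fold change (KO over WT) of the measured members of 12 gene lists in each of 7 cell classes, from 2 libraries per group. Colour follows the printed value and nt marks a list that was not tested. The interferon gamma response median is 1.66 in macrophage-like and 1.96 in neutrophil-like cells, and the MHC class I median is 1.01 and 1.14.

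Whether the change differed between cell types was tested as an interaction of cell type and genotype with the library as a block. Against CD8 T-like cells, 259 of 12205 genes had a different change in macrophage-like cells, 163 higher and 96 lower, and the count was 82 without WT 1, 143 without WT 2 and 90 without KO 1. Against monocyte-like cells, 469 of 11986 genes differed, 255 higher and 214 lower, and 174 without WT 1. The change of the MHC class I list was larger in macrophage-like cells by a median of 0.84 log2 units against CD8 T-like cells (adjusted p = 3.3e-14, and 0.546 with an estimated correlation) and by 0.51 against monocyte-like cells (adjusted p = 1.1e-14, and 0.273 with an estimated correlation). The class II list differed by 0.54 against monocyte-like cells (adjusted p = 0.00213, and 0.473 with an estimated correlation), and by 0.57 against CD8 T-like cells, which did not pass (adjusted p = 0.0514). Of 27 lists, 4 passed with a difference above 0 and 6 with a difference below 0 (macrophage-like minus CD8 T-like cells), and 6 and 10 against monocyte-like cells, none with an estimated correlation. The interferon gamma response list differed by 1.67 against CD8 T-like cells (adjusted p = 5.4e-11, and 0.559 with an estimated correlation) and by 0.81 against monocyte-like cells (1.3e-14, and 0.273). The inflammatory (M1) list, which rose less in macrophage-like cells, differed by -1.09 against CD8 T-like cells (0.00175, and 0.775 with an estimated correlation) and by -1.01 against monocyte-like cells (1.1e-14, and 0.273). The chemokine list differed by -0.80 against CD8 T-like cells (0.000969, and 0.776). In CD8 T-like cells the M1 median was 1.40, with 3 of 14 members passing higher. The chemokine median there was 1.61, with 6 of 17 passing higher. Of the macrophage markers, 14 of 15 also had positive log2 changes in those sums. RNA carried in from macrophages is therefore not separated from a change in CD8 T-like cells. The hypoxia list differed by -0.93 and -1.0 against CD8 T-like and monocyte-like cells (0.000124 and 1.3e-14, and 0.559 and 0.273). Its median was negative in macrophage-like cells (-0.32) and positive in the other 2 classes, where it was higher in KO but changed direction with doublet calls kept in CD8 T-like cells (0.907) and with clusters from all variable genes in monocyte-like cells (0.00726). Differences between the other cell classes were not tested.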

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

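The test that counted clusters, including its bound of 6, the equal cluster weights and the grouping of clusters were chosen only after the result was seen. The change of 259 of 12205 genes differed between macrophage-like and CD8 T-like cells in the test of the difference itself, 163 being higher in macrophage-like cells and 96 lower, and leaving out WT 1, WT 2 or KO 1 gave 82, 143 and 90. Between macrophage-like and monocyte-like cells 469 of 11986 genes differed, 255 higher and 214 lower, and 174 without WT 1. The MHC class I list differed by a median of 0.84 log2 units against CD8 T-like cells and by 0.51 against monocyte-like cells, and the MHC class II list by 0.54 against monocyte-like cells. The interferon gamma response list differed by 1.67 and 0.81 against CD8 T-like and monocyte-like cells. The rise in macrophage-like cells was smaller for the inflammatory (M1) list, by -1.09 and -1.01, and for chemokines against CD8 T-like cells, by -0.80. Macrophage RNA carried into the CD8 T-like sums was not separated from these differences. The hypoxia list differed by -0.93 and -1.0, with a negative median in macrophage-like cells (-0.32) and positive ones in CD8 T-like (0.70) and monocyte-like cells (0.56). It changed direction in CD8 T-like cells with doublet calls kept (0.907) and in monocyte-like cells with clusters from all variable genes (0.00726). The lists beyond MHC were chosen after their values were seen. None of these list differences passed with an estimated correlation, the lowest adjusted p being 0.546 against CD8 T-like and 0.273 against monocyte-like cells.

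The higher interferon gamma response list in macrophage-like cells, with a median log2 change of 1.66, was weighed. Depth as its cause is not decided by thinning. With every cell thinned to 1500 UMIs the median was 1.57, which is 94.6% of its value. It lay inside the range of 1.48 to 1.82 found when 1 library was left out. Cells were thinned only after they had been named at full depth, and thinning scarcely changes the expected CPM of a sum. Median depth in this class showed no consistent gap, at 11483 and 12983.5 UMIs in WT 1 and WT 2 and 9668.5 and 14527 in KO 1 and KO 2. RNA of T cells carried into these barcodes is argued against, since the T cell receptor genes allow it to account for 0.414% of the rise of the median member. A change in how many cells each cluster holds stays open as a part of the rise. With the clusters weighted equally the median was 0.70, or 42.2% of its value, although averaging CPM lets clusters with high levels weigh more. Whether cluster sizes are the whole of the rise was not decided by counting clusters. In 6 of 8 clusters both KO libraries lay above both WT libraries, so levels were higher within those clusters. That count lies exactly on a bound set after the result was seen, and no conclusion is drawn from it. Clusters 4 and 9 were the exceptions, and differences ranged from -0.41 to 1.74. A change of these genes within clusters by genotype was not tested beyond these values.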

How the results depend on the processing

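Total counts, spread of each class alone, named cells only, cluster 1 or low-UMI clusters counted, and equal cluster weights were tests chosen after the data were seen. NK-like sums start at 75095 UMIs. Leaving out a library left a group with 1 library, assumed to vary like the other group. A call gained in such a fit can come from the lost spread of that group. Where a value moved, the cause was not tested unless it is given. No value was obtained for CD8 T-like cells at Leiden resolution 0.5 or for NK-like cells after thinning or at a mitochondrial limit of 10%.

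With the replicate block, 636 genes passed in macrophage-like and 120 in CD4 T-like cells, and the other counts of genes stayed within 1.5 times. Deviations of same-numbered libraries correlated at 0.0214 in macrophage-like, 0.00112 in monocyte-like, 0.0311 in cDC-like and 0.0648 in CD8 T-like cells. They correlated at -0.0138 in CD4 T-like, 0.108 in NK-like and -0.0757 in neutrophil-like cells. The labels do not say whether these libraries shared a day or batch, and low correlations cannot settle it.

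DESeq2 called 310 genes in monocyte-like, 275 in cDC-like, 19 in CD4 T-like, 4 in NK-like and 11 in neutrophil-like cells. With no filter on low counts, which adds genes to the test, 826 passed in cDC-like, 247 in CD8 T-like, 136 in CD4 T-like, 104 in NK-like and 62 in neutrophil-like cells. Thinning gave 224 in monocyte-like, 176 in cDC-like, 15 in CD4 T-like and 55 in neutrophil-like cells. With doublet calls kept 2346 passed in monocyte-like cells, where a cluster like cluster 1 then took that name, and 86 in CD8 T-like cells. The mitochondrial limit of 10% gave 361 in monocyte-like, 199 in CD8 T-like and 6 in neutrophil-like cells, and Leiden resolution 0.5 gave 334 in monocyte-like cells. Clusters from all variable genes gave 204 in monocyte-like, 87 in CD8 T-like and 7 in neutrophil-like cells. Total counts gave 21 in NK-like cells, low-UMI clusters counted gave 151 in CD8 T-like cells, and equal cluster weights 265 in macrophage-like cells. With monocyte-like and macrophage-like cells as 1 class, which also took in the unnamed cluster 1, 1429 passed. Of these, 912 also passed in macrophage-like cells alone in the same direction.

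Leaving out 1 library gave 655 to 1775 genes in macrophage-like, 228 to 609 in monocyte-like, 208 to 863 in cDC-like, 58 to 123 in CD8 T-like, 48 to 148 in CD4 T-like, 10 to 272 in NK-like and 21 to 136 in neutrophil-like cells. The differences between cell types ranged from 82 to 180 genes against CD8 T-like and from 174 to 481 against monocyte-like cells.

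In macrophage-like cells the adjusted p of the MHC class I list was 0.234 with an estimated correlation and 0.0573 in fry, and 2.4e-30 to 8.0e-26 without 1 library. That of the MHC class II list was 0.331, 0.145 and 1.8e-16 to 0.00685. Of 689 other list results 564 kept direction and side of the threshold, 88 lost the call, 14 gained one and 23 changed direction. The M2 list in macrophage-like cells changed direction with total counts (adjusted p = 0.967), without WT 1 (0.679) or KO 1 (0.787), at resolution 0.5 (0.916), with monocyte-like cells added (0.942) and with cluster 1 counted (0.898), and its range without 1 library was 5.2e-05 to 0.787. The type I interferon list did so without WT 1 (0.00835, in a range of 0.00835 to 0.838 without 1 library) and with equal weights (6.5e-05), monocyte-like hypoxia genes with all variable genes (0.00726), and CD8 T-like hypoxia genes with doublet calls kept (0.907). The class II list in cDC-like cells did so with doublet calls kept (0.964), at resolution 0.5 (0.712) and with all variable genes (0.977), and the regulatory T cell list in CD4 T-like cells after thinning (0.862). The dissociation stress list in cDC-like cells, near a median of 0, did so with no filter on low counts (0.906), after thinning (0.495), with doublet calls kept (0.782), at resolution 0.5 (0.188), with all variable genes (0.258), in fry (0.991) and without WT 1, WT 2 or KO 2 (a range of 0.518 to 0.853 without 1 library).

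Log2 changes of shares without 1 library ranged from -2.0 to 0.24 for B-like, 1.89 to 3.06 for NK-like, -0.17 to -0.11 for macrophage-like and -0.69 to 0.77 for neutrophil-like cells. With the spread of each class alone no call held, at 2.59 for CD8 T-like, 2.45 for NK-like, -0.14 for macrophage-like and 1.58 for monocyte-like cells. The macrophage-like change was 0.0390 with TMM over the classes, -0.0203 at a mitochondrial limit of 10% and -0.0155 with low-UMI clusters counted. The monocyte-like change was -0.61 with doublet calls kept, where it passed in the opposite direction (adjusted p = 0.000424). The neutrophil-like change was -0.29 with all variable genes and -0.20 with low-UMI clusters counted. CD4 T-like and cDC-like shares kept direction and side in all 13 alternatives.

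Of 160 named gene results 151 passed, and 7 changed direction in some setting: Oasl2 with equal weights (-0.15), Ndrg1 (-0.26) and Top2a (0.0708) with all variable genes, and with doublet calls kept Spp1 (-0.51) and Arg1 (-0.0474) in CD8 T-like, Tmsb15a (-1.19) in NK-like and Fn1 (0.0164) in neutrophil-like cells. Of 58 named macrophage-like results 19 lost the call with equal cluster weights beside that reversal. Among all named results, 18 of 160 lost it with the replicate block, 26 of 160 in DESeq2 and 1 of 160 with size factors by RLE. Clusters from all variable genes ended it for 27 of 151 and keeping doublet calls for 27 of 158. Others lost it without 1 library.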

Other observations

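The choice to follow mt-Nd3 and Ramp1 across cell classes was made after their values were seen, and no hypothesis was tested on them. The mitochondrially encoded mt-Nd3 (chromosome M, 9459 to 9806), a subunit of complex I, had negative log2 changes in all 7 classes tested. It fell in cDC-like (-0.98, adjusted p = 0.00387), CD8 T-like (-1.20, 0.0143) and NK-like cells (-1.70, 0.000807) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It did not pass in macrophage-like (-1.03, 0.0559), monocyte-like (-1.21, 0.0503), CD4 T-like (-0.50, 0.347) or neutrophil-like cells (-0.91, 0.602). The CD8 T-like and NK-like calls ended without KO 2 (adjusted p = 0.0887 and 0.125). The macrophage-like change was -0.72 without WT 1 and -1.28 without WT 2. The monocyte-like change was -0.82 without WT 1, -1.50 without WT 2, -1.35 without KO 1 and -1.09 without KO 2. The other mitochondrially encoded genes did not share this fall in every class. Of the 13 measured, mt-Nd3 included, 11 had positive log2 changes in macrophage-like, 5 in monocyte-like, 9 in cDC-like, 10 in CD8 T-like and 11 in CD4 T-like cells, as did 3 of 12 in NK-like and 2 of 10 in neutrophil-like cells. In CD4 T-like cells mt-Atp6, mt-Co2, mt-Cytb and mt-Nd2 rose and none fell (9 higher and 1 lower adjusted over the list alone; median 0.45, camera adjusted p = 8.9e-09, and 0.350 with an estimated correlation). In cDC-like cells mt-Nd4l also passed, higher in KO. In NK-like cells the list was lower (median -0.14, camera adjusted p = 0.0175, and 0.406 with an estimated correlation) with mt-Nd3 alone passing, and it lost its call without WT 2, KO 1 or KO 2 (adjusted p up to 0.185) and with doublet calls kept (0.197). Ramp1, which encodes a partner of the calcitonin receptor-like receptor, fell in macrophage-like (-1.31), CD8 T-like (-1.91) and CD4 T-like cells (-2.59), the CD8 T-like call ending without WT 2 (-1.30, adjusted p = 0.318).

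Over all kept cells the Y-linked genes Ddx3y and Eif2s3y were at 49.3 and 45.0 CPM in WT 1, 49.5 and 49.3 in WT 2, 53.1 and 40.6 in KO 1 and 95.2 and 88.5 in KO 2. Uty and Kdm5d were also highest in KO 2, at 21.1 and 17.2 CPM. Whether the hosts differed in sex between libraries could not be told from the labels. Such a difference is therefore not separated from genotype in the comparisons above. The haemoglobin gene Hbb-bs, a sign of erythroid RNA, was at 2.09 and 0.506 CPM in WT 1 and WT 2, and at 0.0969 and 0.0109 CPM in KO 1 and KO 2.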
